A study of Mus musculus with 12 samples.

How the data were processed

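The 12 arrays measured lung tissue of female C57BL/6N mice, 3 arrays in each of 4 groups: smoke-exposed and control mice at 4 months and at 6 months of age. Per the labels' protocols, total RNA was prepared with RNeasy Mini columns and a DNase step, and the RNA was labelled with biotin through an Illumina TotalPrep kit before it was hybridised to Illumina mouse bead arrays. An Illumina bead array reads the brightness of many beads that carry the same probe. The labels call the samples biological replicates. Groups and replicate numbers were taken from the sample titles.

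Per the file headers, the authors deposited for each array a raw probe intensity on a linear scale, which runs below 0 for 18.3 to 21.0% of the probes of an array, and with it a detection p-value for each probe. Negative values show that a background had been subtracted before the authors deposited the table. The scanner software, the method of that subtraction and the normalization of the authors' second table are not given in the sources used here. From its values, the deposited second table holds linear intensity of the same arrays. Its medians were 49 to 50 on every array, its sorted columns differed by at most 110 intensity units, and its rank correlation with the raw intensity of the same array was at least 0.9999, as after quantile normalization with an offset. Its log2 fold changes correlated across probes with those used here at r = 0.995 at both ages (genes are not independent replicates).

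Both tables held 25697 probes. The platform annotation gave 1 gene symbol for 23978 probes and several for 0, and 1719 probes are unnamed here. Symbols were updated through gene identifiers, of which 23962 were found in a RefSeq table that was used for names only, so no coordinates are given. The named probes carried 16593 symbols.

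The raw intensity was corrected for background with the normal-exponential model of limma (nec, with the negative controls inferred from the detection p-values, which took 798 steps), raised by an offset of 16, quantile normalized and put on the log2 scale (neqc). The offset understates the changes of dim probes. Probes with a detection p below 0.05 on at least 3 of the 12 arrays were kept, which left 15490 probes, 900 of them unnamed, and 10541 named genes. For the 2901 genes with over 1 such probe, the probe with the highest mean over all arrays stood for the gene. Where another probe of a named gene moved the other way, the text says so for any gene that passed.

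A linear model with 1 mean per group was fitted to all 12 arrays with limma's lmFit, and eBayes moderated the variances (8 residual and 4.54 prior degrees of freedom). The contrasts were smoke against control at each age, their average, their difference (6 minus 4 months), and 6 against 4 months within the control and within the smoke arrays. All p-values were two-sided and were adjusted by Benjamini-Hochberg over the 15490 probes, and an adjusted p below 0.05 counted as passing. A probe that no array of a group detected has only a bound there. Its change is then given as at least N-fold, the mean log2 value of the brighter group against the mean, over the arrays of the dimmer group, of the higher of that probe's own value and the lowest value of any detected probe on the array. A list's median was computed again with such genes at their bound, and is given where it differed by over 0.015 in a list that passed.

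Gene lists for lung, blood and neighbouring tissues and for pathways, 44 in all, were fixed before the data were examined, as were the contrasts, the tests, the filter, the alternatives and the rule for naming genes. Lists with at least 4 tested genes, 42 of them, were tested with limma's camera at its preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast. Each list's members were also adjusted among themselves. Camera was repeated with the correlation estimated from the data, and fry was run as another tool. Some genes stand in several lists, for example Saa3 among the cytokines and among the acute phase genes.

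The genes named are, at each age, the 10 with the largest rise and the 8 with the largest fall among those that passed and whose 3 smoke arrays all lay on one side of the 3 control arrays, and 5 and 5 by the same rule for each change with age and for the difference (with no demand on separation there). For each list described, up to 4 tested members with the smallest p are named. Named at both ages, whether they changed or not, are Ms4a1, Cd79a, Cxcl13, Ccl19, Ltb, Tnfsf13b, Mmp12, Mmp9, Ccl2, Cyp1a1, Cyp1b1, Nqo1, Cd68, Itgax, Saa3, Sftpc, Scgb1a1 and Eln. Some other genes of that fixed set are not reported here. Symbols are printed only for probes with 1 symbol. Genes named outside this rule are said to be chosen after their values were seen.

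The alternatives were the authors' deposited values, no further background correction, an offset of 50, scaling to equal medians or cyclic loess in place of quantile normalization, no filter, detection p below 0.01 on all 12 arrays, eBayes with trend and robust spread, array weights, the replicate number as a block, the mean of a gene's probes, a fit of only the arrays compared, an estimated correlation, fry, and leaving out each array in turn. A slide or scan date, planned as a block, is not used here because no source gave one.

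The steps were tested on simulated data built from these arrays, with 10541 genes in each run. For smoke against control at 4 months, 46.3% of genes changed 1.5-fold, 85.1% of those changed 2-fold and 100% of those changed 4-fold were recovered, with 9 false calls. At 6 months the shares were 56.7%, 86.6% and 100%, with 15 false calls. For 6 against 4 months in control mice they were 47.8%, 85.1% and 98.5%, with 8 false calls, and for the difference between ages 30.6%, 73.1% and 99.2%, with 15 false calls. In no run was a changed gene called in the wrong direction. Camera called all 3 lists shifted by 0.5 log2 units at each age and 0 others. The simulated probes varied independently and with the same spread on every array, unlike the real ones. The runs therefore do not show how often camera calls lists of correlated genes falsely. Other splits of the real 4-month arrays called up to 23 lists. R 4.3.3 with limma 3.58.1 was used for all tests, and Python 3.11.15 with matplotlib 3.10.9 for the figures. Replicate arrays of a group shared identical values at no more than 4.53% of probes, so none is a copy of another. Each array was counted as a separate sample because the labels call the samples biological replicates.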

Results

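RNA of whole lung tissue was measured on 12 Illumina mouse bead arrays, from female C57BL/6N mice exposed to cigarette smoke and from control mice. The mice were 4 or 6 months old, with 3 arrays in each of the 4 groups. The series asks how smoke brings about lymphoid tissue in the lung, with its B cells, and the activation of macrophages in a mouse model of chronic obstructive pulmonary disease. The labels call the samples biological replicates and give no time of collection, and the number of arrays limits the precision. Median raw intensities were 18 to 28 per array, and 55.1 to 57.6% of probes were detected. Levels below are normalized log2 intensities as mean ± SD (n = 3), and changes are log2 fold changes, smoke minus control.

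At 4 months, smoke-exposed lungs held far more RNA of macrophage genes than control lungs. Mmp12, the elastase of macrophages, rose by 3.47, from 6.67 ± 1.02 to 10.15 ± 0.34 (n = 3). Gpnmb, a glycoprotein of macrophage lysosomes, rose by 3.39 (9.56 ± 0.50 to 12.95 ± 0.17) and Ctsk, the protease cathepsin K, by 2.75 (9.41 ± 0.38 to 12.17 ± 0.16). Trem2, a lipid-sensing receptor of macrophages, rose by 2.58 (6.76 ± 0.04 to 9.34 ± 0.27). Ccl3, a chemokine that attracts monocytes, rose by 2.63 (6.05 ± 0.28 to 8.68 ± 0.27), Wfdc17 by 2.88 and the chemokine receptor Cxcr1 by 2.51. Ear6, a ribonuclease of eosinophils, and Npy, neuropeptide Y, rose by 2.68 and 2.65, each detected on 1 of the 3 control arrays. Dbp, an output gene of the circadian clock, rose by 3.05 (8.10 ± 0.30 to 11.15 ± 0.29). The limma adjusted p of these 10 genes, the largest rises, lay between 2.97e-06 (Gpnmb) and 0.00446 (Ear6).

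Several groups of genes rose with them at 4 months. In the list of lysosome and lipid handling, 12 of 30 tested genes were higher and 18 did not pass (18 higher adjusted over the list alone; median 0.36, camera adjusted p = 1.46e-21), led by Gpnmb, Trem2, Lgals3 (0.88) and Ctsz (1.01). Among cytokines and chemokines, 12 of 29 were higher and 17 did not pass (17 higher adjusted over the list alone; median 0.77, camera adjusted p = 4.64e-18), with Ccl3, Ccl6 (2.43), Ccl7 (2.14) and Ccl2 (1.63, detected on 1 control array). Among markers of monocytes and other macrophages, 9 of 19 were higher (10 higher and 1 lower adjusted over the list alone; median 0.66, camera adjusted p = 1.12e-09), with Trem2, Ms4a7 (1.87) and Adgre1 (1.17). Of the 13 alveolar macrophage markers 5 were higher, 1 lower and 7 did not pass (7 higher and 2 lower adjusted over the list alone; median 0.35, camera adjusted p = 3.7e-07), with Ctsk, the scavenger receptor Marco (1.58) and Itgax (1.12), the integrin CD11c, among the higher. Proteases and their inhibitors were higher in 5 of 21 genes (6 adjusted over the list alone; median 0.16, camera adjusted p = 0.000871). Without control replicate 2 at 4 months the medians of the cytokine, monocyte and protease lists were 0.47, 0.41 and 0.05. The protease median was 0.09 both without smoke replicate 3 and without control replicate 3.

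Genes of acute inflammation and of the response to smoke chemicals were also higher at 4 months. Saa3, an acute phase serum amyloid, rose by 2.49 (8.36 ± 0.49 to 10.85 ± 0.33, limma adjusted p = 0.000951), and 2 of the 15 complement and acute phase genes were higher (6 adjusted over the list alone; median 0.23, camera adjusted p = 2.01e-06). That median was 0.36 without smoke replicate 1 and 0.35 without control replicate 3. Cyp1b1, an enzyme induced through the aryl hydrocarbon receptor, rose by 1.09 (limma adjusted p = 0.00256). Nqo1, a quinone reductase under NRF2, rose by 0.72 (limma adjusted p = 0.0208) and Slc7a11, the cystine transporter, by 1.27 (limma adjusted p = 0.00285). The aryl hydrocarbon receptor targets were higher in 2 of 7 genes (4 adjusted over the list alone; median 0.57, camera adjusted p = 1.24e-05). The NRF2 and oxidative stress genes were higher in 3 of 29 (7 adjusted over the list alone; median 0.22, camera adjusted p = 5.68e-07). Cyp1a1 was not tested. The call of Nqo1 was lost without smoke replicates 1, 2 or 3 (adjusted p = 0.0528, 0.0954 and 0.105).

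Interferon and cytotoxic lymphocyte genes went the other way at 4 months. Of 24 interferon response genes 2 were lower and 22 did not pass (11 lower adjusted over the list alone; median -0.32, camera adjusted p = 3.7e-07), led by Oas2, an antiviral enzyme, at 6.83 ± 0.24 against 7.83 ± 0.17 in controls (n = 3, limma adjusted p = 0.00919). Of 12 markers of NK and cytotoxic cells 2 were lower (4 adjusted over the list alone; median -0.37, camera adjusted p = 8.23e-05), led by the receptor Klrd1 at -0.61 (limma adjusted p = 0.0235). Of 5 mast cell and basophil markers 1 was lower, Gata2 at -0.65 (3 adjusted over the list alone; median -0.52, camera adjusted p = 0.00216). The call of Gata2 (limma adjusted p = 0.0365) was lost without any 4-month array but control replicate 3. It was also lost without smoke replicate 3 or control replicates 2 or 3 at 6 months (0.0502 to 0.15 over all these). The call of Oas2 was lost without smoke replicate 2 (adjusted p = 0.0506) or 3 (0.0602). That of Klrd1 was lost without smoke replicates 2 (0.121) or 3 (0.132) or control replicates 1 (0.0634) or 2 (0.0753).

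The largest falls at 4 months were those of Spon2, a secreted matrix protein, at -1.76 (10.92 ± 0.08 against 12.68 ± 0.28 in controls), and of Avpr1a, a vasopressin receptor, at -1.63 (5.57 ± 0.17 against 7.21 ± 0.05). The other 6 of the 8 largest included Gp5 (-1.48), Itga2b (-1.41) and Treml1 (-1.33), which platelets carry on their surface. Cidec (-1.43), a lipid droplet protein, Asgr1 (-1.32) and the clock gene Npas2 (-1.20, detected on 2 of the 3 smoke arrays) completed them. The limma adjusted p of these 8 genes lay between 6.53e-05 (Spon2) and 0.0294 (Cidec). Eln, which encodes elastin, was at -0.58 (9.31 ± 0.25 against 9.89 ± 0.10, limma adjusted p = 0.0436). The calls of Gp5, Cidec, Itga2b, Treml1 and Asgr1 were all lost without smoke replicate 1 (adjusted p 0.0709 to 0.113) and without smoke replicate 2 (0.0602 to 0.096). All but Gp5 were lost without smoke replicate 3 (0.0602 to 0.136), all but Asgr1 without control replicate 1 (0.0644 to 0.123), and Cidec, Itga2b and Asgr1 without control replicate 2 (0.0632 to 0.0936). The call of Eln held without smoke replicate 1 at 4 months or control replicate 1 at 6 months and was lost without each of the other 10 arrays (adjusted p 0.0508 to 0.202).

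B cell and lymphoid tissue genes did not pass as groups at 4 months. The B cell list had a median of 0.04 over 19 tested genes, none of which passed in limma (camera adjusted p = 0.0919), with Ms4a1, the CD20 antigen, at 0.36 and Cd79a, part of the B cell receptor, at 0.04. The camera call of that list appeared without smoke replicate 2 (median 0.16, adjusted p = 0.0132) or control replicate 1 (0.29, 1e-04). Of the 25 genes of lymphoid tissue formation 1 was higher, Fcamr, a receptor for IgM and IgA, by at least 1.29-fold (limma adjusted p = 0.0124; 0.0682 without smoke replicate 1 and 0.0745 without smoke replicate 2), and the list's median was 0.05 (camera adjusted p = 0.459). Cxcl13 and Ccl19, chemokines that draw lymphocytes into follicles, were at 0.57 and 0.67 and did not pass (limma adjusted p = 0.446 and 0.301). Nor did Ltb at -0.12 or Tnfsf13b, the B cell survival factor BAFF, at -0.05. The plasma cell list had 1 higher gene of 9, Fkbp11 at 0.74 (limma adjusted p = 0.0162), a median of -0.08, a mean of 0.12 and a test upward (camera adjusted p = 0.288; 0.0132 with a median of 0.24 without control replicate 1). Fkbp11 no longer passed without smoke replicates 2 (0.0824) or 3 (0.0992) or control replicate 2 (0.0705). The germinal centre and T cell lists had medians of -0.08 and -0.16 (camera adjusted p = 0.689 and 0.31). The call of the T cell list appeared without control replicate 2 (median -0.53, adjusted p = 4.73e-07). Cd68 had no probe under that name and was not tested. Mmp9 was at -1.35, Sftpc, a surfactant protein, at 0.15 and Scgb1a1, the club cell secretory protein, at -0.04, and none of the 3 passed (limma adjusted p = 0.273, 0.563 and 0.86). Mmp9 was at -0.80 without control replicate 1, and Cxcl13 and Ccl19 at 0.31 and 0.41 without control replicate 2.

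Counted over all genes, limma with Benjamini-Hochberg adjustment called 174 of 10541 genes at 4 months, 135 higher and 39 lower, of which 68 and 15 changed at least 2-fold. In 21.4% of all genes, against 10% by chance, the 3 smoke arrays all lay on one side of the 3 control arrays. This share does not by itself speak for smoke. Between 6 and 4 months it was 22.2% in smoke arrays, where 2 genes passed, and 16.7% in control arrays, where 6 passed. The count was 102, 96 and 87 without smoke replicates 1, 2 and 3, 371 without control replicate 3 and 648 with array weights. Camera called 19 of 42 lists. The alveolar type 2 list (median 0.17, adjusted p = 0.000103; no gene of 20 passed over all genes, 2 higher adjusted over the list alone) was among the 12 lists that also passed with an estimated correlation. Endothelial markers were lower as a group (median -0.25 over 24 genes, camera adjusted p = 0.00184, adjusted p = 0.307 with an estimated correlation), with none passing singly in limma or adjusted over the list alone. Camera calls more lists than this in some other splits of the same 6 arrays, up to 23.

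**Figure D1:**
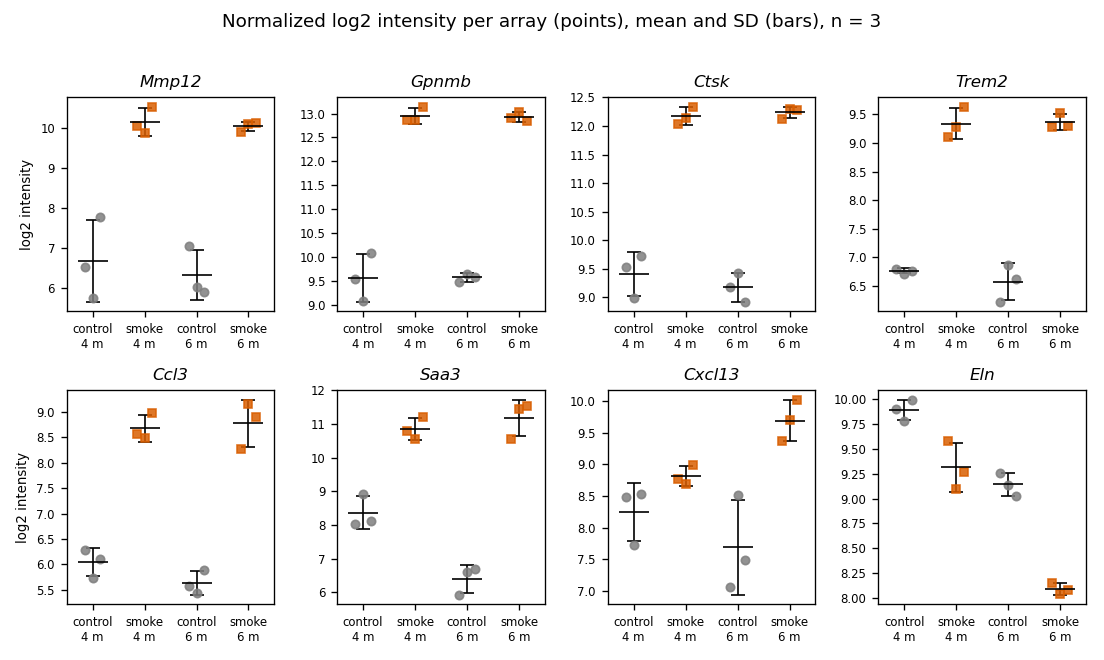
Normalized log2 intensity of 8 genes (vertical axis) in the 4 groups, with a point for each array and bars for the mean ± SD of 3 arrays. Mmp12 lies at 10.15 ± 0.34 and 10.04 ± 0.12 in smoke-exposed lungs at 4 and 6 months against 6.67 ± 1.02 and 6.32 ± 0.63 in controls, and Eln at 9.31 ± 0.25 and 8.09 ± 0.06 against 9.89 ± 0.10 and 9.14 ± 0.12.

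At 6 months, Saa3 had the largest rise, 4.77, from 6.40 ± 0.41 to 11.17 ± 0.54 (n = 3). Mmp12 rose by 3.72 (6.32 ± 0.63 to 10.04 ± 0.12) and Gpnmb by 3.36 (9.57 ± 0.09 to 12.93 ± 0.10). Ccl3 rose by 3.14 (5.64 ± 0.23 to 8.78 ± 0.46) and Ctsk by 3.06 (9.17 ± 0.25 to 12.24 ± 0.10). Cd177, a surface protein of neutrophils, rose by 3.30 (7.50 ± 0.26 to 10.80 ± 0.03) and Cxcl1, a chemokine that draws neutrophils, by 3.15 (6.41 ± 0.26 to 9.56 ± 0.24). The acute phase gene Orm1 rose by 3.11 and Ear6, detected on 2 control arrays, by 3.07. Npy, which no control array detected, was at least 6.90-fold higher. The limma adjusted p of these 10 genes lay between 1.87e-06 (Gpnmb and Ctsk) and 0.00224 (Cd177). The neutrophil list, which holds neither Cd177 nor Cxcl1, did not pass camera at 6 months (median -0.23).

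Macrophage and inflammation lists rose at 6 months. Of 29 cytokines and chemokines 19 were higher and 10 did not pass (22 higher adjusted over the list alone; median 1.32, or 1.08 with genes at their bounds; camera adjusted p = 1.26e-26), with Saa3, Ccl3, Ccl4 (2.00) and Ccl7 (2.45, detected on 2 control arrays), and Ccl2, which no control array detected, at least 2.11-fold higher. Lysosome and lipid handling genes were higher in 17 of 30 (22 higher and 1 lower adjusted over the list alone; median 0.57, camera adjusted p = 3.53e-20), with Lgals3 at 1.12 and Ctsz at 1.26. Alveolar macrophage markers were higher in 8 of 13 (9 higher and 2 lower adjusted over the list alone; median 0.59, camera adjusted p = 2.28e-08), with Marco at 2.05 and F7 at 1.08. Itgax was at 0.59 (limma adjusted p = 0.0488), a call that held without smoke replicate 1 at 4 months or smoke replicate 2 at 6 months and was lost without each of the other 10 arrays (adjusted p 0.0526 to 0.184). Markers of monocytes and other macrophages were higher in 9 of 19 and lower in 1 (11 higher and 1 lower adjusted over the list alone; median 0.74, camera adjusted p = 1.14e-09, adjusted p = 0.0589 with an estimated correlation), with the complement subunits C1qa (1.46) and C1qc (1.54). Complement and acute phase genes were higher in 6 of 15 (6 adjusted over the list alone; median 0.26, camera adjusted p = 2.43e-05). Proteases and inhibitors were higher in 6 of 21 (8 higher and 1 lower adjusted over the list alone; median 0.32, camera adjusted p = 8.75e-05). The complement median was 0.17 without smoke replicate 2.

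Camera called the lists of cell cycle, of plasma cell and immunoglobulin, and of MHC class II and dendritic cell genes higher at 6 months. None of these calls held with an estimated correlation. In the cell cycle list 12 of 25 genes were higher and 13 did not pass (19 higher adjusted over the list alone; median 0.49, camera adjusted p = 4.52e-15, adjusted p = 0.0871 with an estimated correlation), with Uhrf1 at 1.12, Top2a, a topoisomerase of dividing cells, at 1.05, and Tk1 at 1.04, whose other probe went down and whose mean over probes did not pass (limma adjusted p = 0.171; 0.00106 to 0.171 over all alternatives). Among plasma cell and immunoglobulin genes 3 of 9 were higher (6 adjusted over the list alone; median 0.79, or 0.70 with genes at their bounds; camera adjusted p = 1.07e-06, adjusted p = 0.115 with an estimated correlation). They were Fkbp11 (1.21), Pigr (1.86), the receptor that carries IgA across epithelium, and Tnfrsf17, the plasma cell receptor BCMA, at least 2.38-fold. None of these 3 is an immunoglobulin gene. The call of Tnfrsf17 (limma adjusted p = 0.0205) was lost without smoke replicates 2 (0.0799) or 3 (0.0962) and without control replicates 1 (0.0585), 2 (0.0642) or 3 (0.0583). MHC class II and dendritic cell genes were higher in 4 of 22 (7 adjusted over the list alone; median 0.23, or 0.20 with genes at their bounds; camera adjusted p = 0.000163, adjusted p = 0.254 with an estimated correlation), with Clec4n (1.81), Itgae (0.98), Fscn1 (1.23) and Cd86 (0.86). None of these 4 encodes an MHC class II molecule. The call of Cd86 (limma adjusted p = 0.0143) was lost without smoke replicates 2 (0.0575) or 3 (0.0612) or control replicate 1 (0.0544).

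Cxcl13 rose by 2.00 at 6 months, from 7.69 ± 0.75 to 9.69 ± 0.33 (limma adjusted p = 0.00313), and Ccl19 by 1.35, from 7.20 ± 0.41 to 8.55 ± 0.42 (limma adjusted p = 0.0143). Of the 25 lymphoid tissue genes 4 were higher and 21 did not pass (6 higher adjusted over the list alone), and the list's median was 0.08 (camera adjusted p = 0.0251, adjusted p = 0.371 with an estimated correlation). Ltb and Tnfsf13b did not pass, at 0.42 and 0.17. The B cell list had a median of 0.07 and did not pass (camera adjusted p = 0.155), with 2 of 19 genes higher (3 adjusted over the list alone), Blnk, a B cell adaptor protein, at 0.90 (limma adjusted p = 0.00566; 0.0511 for the mean of its probes and 0.00151 to 0.0511 over all alternatives) and Vpreb3 at 0.64 (limma adjusted p = 0.0111), while Ms4a1 was at -0.17 and Cd79a at 0.07. The germinal centre and T cell lists were at 0.08 and 0.06 (camera adjusted p = 0.99 and 0.174), and the T cell list passed without control replicate 3 (0.26, 0.0492). The call of Ccl19 was lost without smoke replicates 2 (0.0592) or 3 (0.0744) or control replicates 1 (0.067) or 3 (0.0505), and that of Vpreb3 without control replicate 1 (0.0508). That of the lymphoid list was lost without smoke replicate 3 (median 0.03, 0.0864) or control replicate 1 (0.03, 0.143), while the B cell list passed without smoke replicate 1 (0.15, 0.00716).

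Cyp1b1 rose by 1.24 at 6 months (limma adjusted p = 0.000494), and Ahrr, the repressor of the same receptor, was at least 1.22-fold higher (limma adjusted p = 0.027; 0.117 without smoke replicate 2 and 0.0768, 0.0695 and 0.0655 without control replicates 1, 2 and 3). The aryl hydrocarbon receptor targets were higher in 2 of 7 (4 adjusted over the list alone; median 0.50, or 0.32 with genes at their bounds; camera adjusted p = 0.0021, adjusted p = 0.138 with an estimated correlation). The NRF2 list was higher in 4 of 29 (6 adjusted over the list alone; median 0.20, camera adjusted p = 0.000202), with Slc7a11 at 1.68, detected on 1 control array, and Hmox1, heme oxygenase, at 1.52. Nqo1 was at 0.50 and did not pass (limma adjusted p = 0.0643; 0.0288 without control replicate 3 at 4 months). The alveolar type 2 list was higher (2 of 20, 5 adjusted over the list alone; median 0.14, camera adjusted p = 0.00306), with Chil1 at 0.84, while Sftpc was at 0.01 and Scgb1a1 at 0.01. Mmp9 was at -0.18 (limma adjusted p = 0.922).

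The largest falls at 6 months were those of Spon2 at -1.77 (9.96 ± 0.28 against 11.73 ± 0.14 in controls), of the clock gene Arntl at -1.74 (6.21 ± 0.12 against 7.95 ± 0.48), and of Gdpd2 at -1.69. They were followed by Asgr1 at -1.52, the clock-linked factor Nfil3 at -1.44, Adm, a vasodilator peptide, at -1.41, Avpr1a at -1.40 and Angptl4, an inhibitor of lipoprotein lipase, at -1.36. The limma adjusted p of these 8 genes lay between 5.55e-05 (Spon2) and 0.0301 (Angptl4). The call of Angptl4 was lost without smoke replicates 1 (0.0953) or 3 (0.104) or control replicate 2 (0.0985). Eln fell by 1.06, from 9.14 ± 0.12 to 8.09 ± 0.06 (limma adjusted p = 0.000444), and Lox, which crosslinks elastin and collagen, by 0.69 (limma adjusted p = 0.0042). At 4 months Lox had gone the other way, at 0.48, and did not pass (limma adjusted p = 0.0673). It passed there as higher without control replicate 3 at 4 months (0.59, limma adjusted p = 0.0173). Extracellular matrix and fibroblast genes were lower in 4 of 29 (1 higher and 7 lower adjusted over the list alone; median -0.20, camera adjusted p = 0.00306, adjusted p = 0.254 with an estimated correlation). Glucocorticoid targets were lower in 7 of 13 (8 adjusted over the list alone; median -0.89, camera adjusted p = 4.74e-07), with Tsc22d3, the leucine zipper GILZ, at -0.89 and Errfi1 at -1.18. Endothelial markers were lower as a group (1 of 24, 2 adjusted over the list alone; median -0.27, camera adjusted p = 7.86e-07, adjusted p = 0.0871 with an estimated correlation). The 1 endothelial gene that passed, Tek (-0.53, limma adjusted p = 0.048), passed without control replicate 2 at 6 months and was lost without each of the other 11 arrays (adjusted p 0.0545 to 0.166). The matrix list no longer passed without smoke replicate 2 (median -0.10, 0.0544).

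Over all genes at 6 months, limma with Benjamini-Hochberg adjustment called 535 of 10541, 353 higher and 182 lower, of which 136 and 22 changed at least 2-fold. In 21.7% of all genes, against 10% by chance, smoke and control arrays did not overlap, a share no larger than the 22.2% between the ages in smoke arrays. The count was 316 and 273 without smoke replicates 2 and 3 and 347 without control replicate 1. Camera called 22 of 42 lists, 8 of them with an estimated correlation: cytokines, lysosome, alveolar macrophages, glucocorticoid targets, complement, proteases, NRF2 and alveolar type 2.

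**Figure D2:**
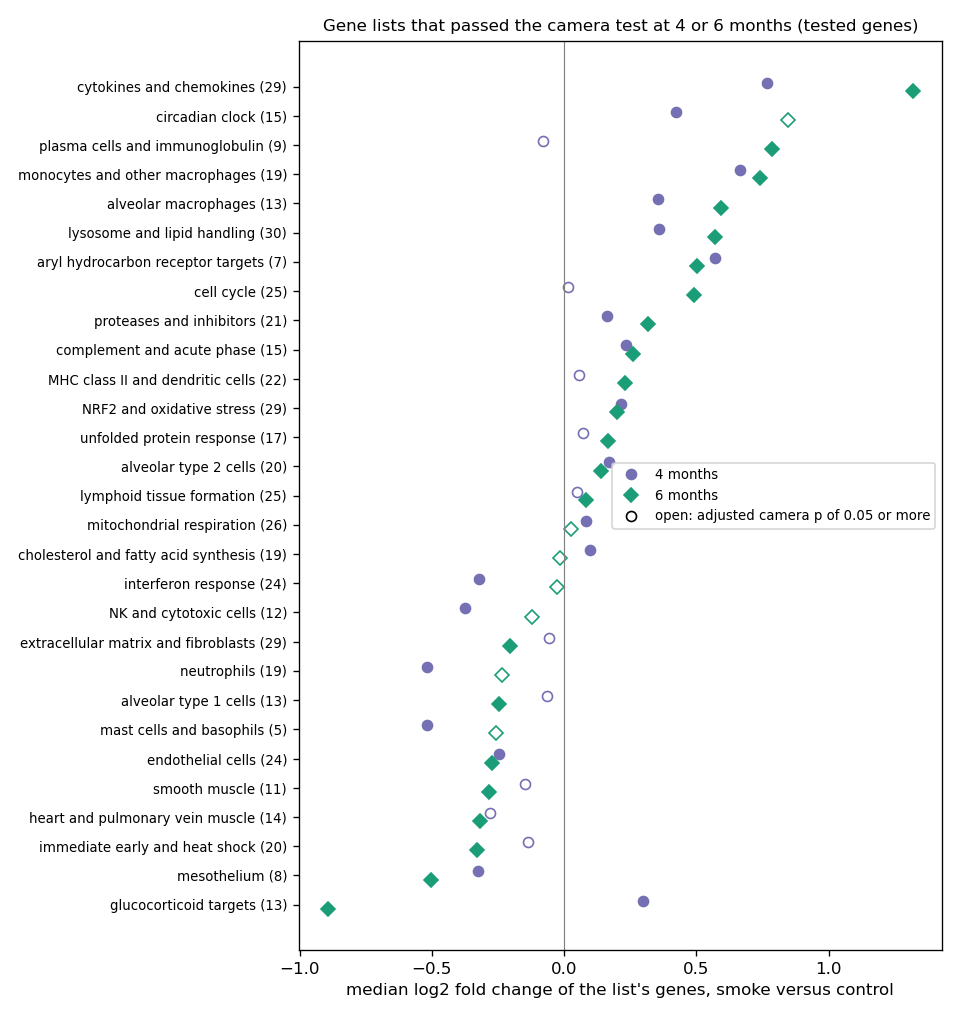
Median log2 fold change, smoke against control, of the 29 lists that passed camera at either age, with circles for 4 months, diamonds for 6 months and open symbols where the adjusted p was 0.05 or more. Cytokines and chemokines lie farthest to the right at 0.77 and 1.32, and glucocorticoid targets move from 0.30 to -0.89.

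Many genes were called at both ages. Of the genes called at each age, 120 were higher and 22 lower at both, where independent lists of the same sizes would share 4.52 and 0.673, and 0 were called in opposite directions. Among them were Mmp12, Gpnmb, Ctsk, Trem2, Ccl3, Saa3, Marco, Cyp1b1 and Dbp, higher, and Spon2, Avpr1a, Asgr1 and Eln, lower. The 2 comparisons share no arrays but use the same variance estimate of each gene, so their calls are not fully independent. Of the 174 genes called at 4 months, 168 had the same sign at 6 months, and of the 535 called at 6 months, 479 had the same sign at 4 months. Across all genes the fold changes correlated at r = 0.558 (genes are not independent replicates). In the average over both ages limma called 734 genes, 453 higher and 281 lower. The shared count was 90 and 82 without smoke replicates 2 and 3 at 4 months and 222 with array weights. The averaged count was 451 without smoke replicate 3 at 4 months, 486 and 469 without smoke replicates 2 and 3 at 6 months, and 1252 with array weights.

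**Figure D3:**
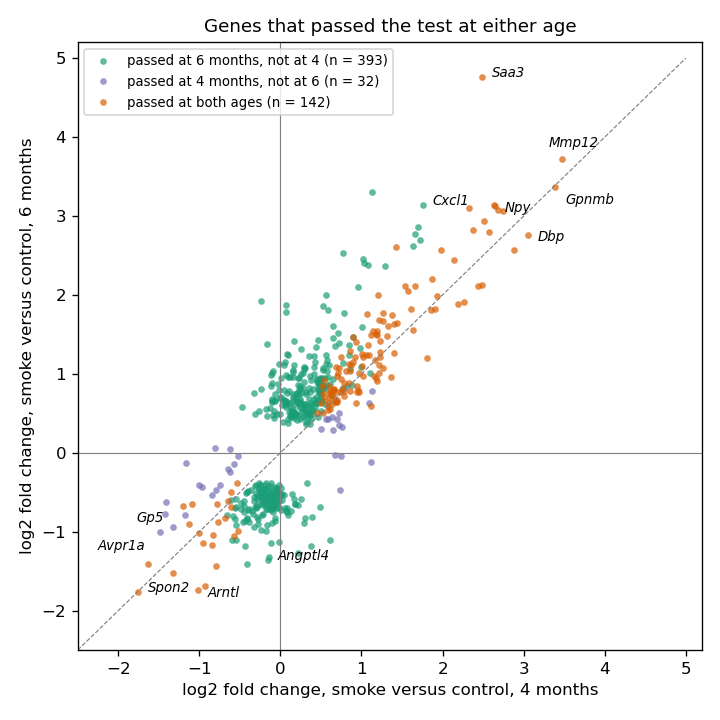
Log2 fold change, smoke against control, at 4 months (horizontal axis) and at 6 months (vertical axis), with a point for each gene that passed at either age and a dashed line where both are equal. The 142 genes that passed at both ages have the same sign at both, 393 passed at 6 and not at 4 months, and 32 at 4 and not at 6 months.

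Genes of the circadian clock were among those that changed at both ages. Dbp rose by 3.05 at 4 and 2.76 at 6 months, Nr1d2 by 1.36 and 0.96, and Bhlhe40 by 0.97 and 1.01, while Npas2 fell by 1.20 at 4 months and was at least 1.45-fold lower at 6 months, where no smoke array detected it. Of 15 clock genes, 5 were higher, 3 lower and 7 did not pass at 4 months (7 higher and 4 lower adjusted over the list alone; median 0.42, camera adjusted p = 0.0201, adjusted p = 0.338 with an estimated correlation). Of the same 15, 7 were higher and 4 lower at 6 months (8 and 4 adjusted over the list alone; median 0.85, camera adjusted p = 0.104). The labels give no time of day. The 4-month median was 0.69 without control replicate 2 and 0.15 (adjusted p = 0.149) without control replicate 3.

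**Figure D4:**
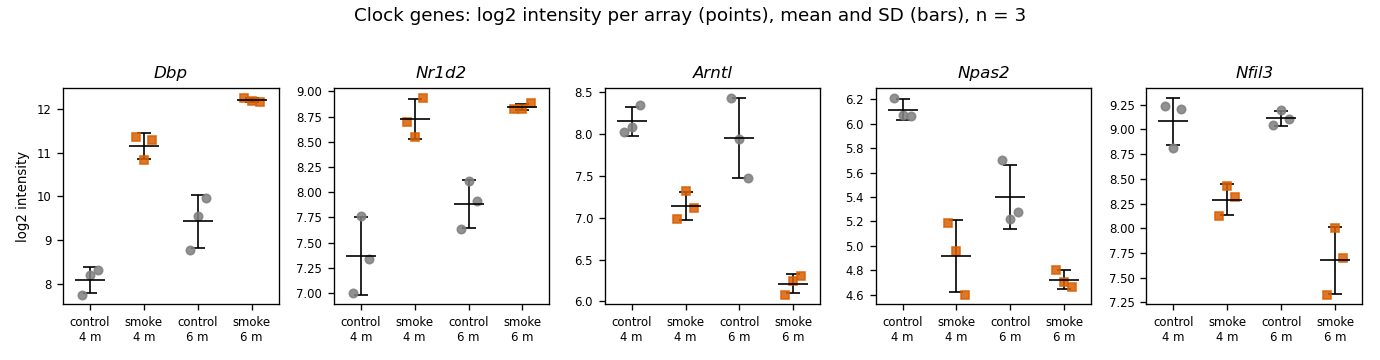
Normalized log2 intensity of 5 clock genes (vertical axis) in the 4 groups, with a point for each array and bars for the mean ± SD of 3 arrays. Dbp lies at 11.15 ± 0.29 in smoke-exposed and 8.10 ± 0.30 in control lungs at 4 months, and Arntl at 6.21 ± 0.12 and 7.95 ± 0.48 at 6 months.

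The difference of the smoke effect between the ages was tested by itself. No single gene passed: limma called 0 of 10541 genes, with 875 at an unadjusted p below 0.05 and a smallest adjusted p of 0.142 (Lox, -1.17). Lists did differ by camera. Cell cycle genes had a larger smoke effect at 6 months by a median of 0.56 (13 higher adjusted over the list alone, camera adjusted p = 2.04e-12, adjusted p = 0.447 with an estimated correlation), and plasma cell genes by 0.78 (1 higher, 0.000152, adjusted p = 0.696 with an estimated correlation). Cytokines had a larger one by 0.42 (4 higher, 3.05e-05, adjusted p = 0.713 with an estimated correlation). At the preset correlation the cytokine list was lower at 6 than at 4 months in the control arrays (median -0.40, camera adjusted p = 0.000709). In the smoke arrays its change did not pass (0.10, 0.319). Interferon genes, lower under smoke at 4 months at -0.32 and at -0.03 at 6 months, differed by 0.32 (5 higher, camera adjusted p = 2e-06, adjusted p = 0.0993 with an estimated correlation). Glucocorticoid targets differed by -1.08 (8 lower adjusted over the list alone, camera adjusted p = 1.87e-11, also passing with an estimated correlation). Differences of Uhrf1, Saa3 and Tsc22d3 were 1.07, 2.28 and -1.19, none of which passed alone. For these lists chance cannot be excluded, as other groupings of the same arrays by age gave up to 22 lists. The plasma cell difference was 0.46 without control replicate 1 at 4 months and 0.49 without smoke replicate 3 at 6 months.

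With age, limma called 6 genes between 6 and 4 months in control mice (1874 at an unadjusted p below 0.05). Saa3 was lower at 6 months by -1.96 (6.40 ± 0.41 against 8.36 ± 0.49) and Hsd3b2, a steroid dehydrogenase, by -1.79 (8.74 ± 0.24 against 10.53 ± 0.65). Xist, the RNA that silences an X chromosome, was lower by -1.71 (5.47 ± 0.38 against 7.18 ± 0.21) and Cemip2 by -0.86 (10.35 ± 0.10 against 11.21 ± 0.12). Apoa2 was at least 1.61-fold lower and Arhgap10 at least 1.51-fold higher. The limma adjusted p were 0.0159 (Xist), 0.0463 (Saa3) and 0.03 (the other 4). In smoke-exposed mice limma called 2 genes (1141 at an unadjusted p below 0.05): Eln fell by 1.23 (8.09 ± 0.06 against 9.31 ± 0.25, adjusted p = 0.00582) and Xist by 1.51 (5.83 ± 0.03 against 7.34 ± 0.32, adjusted p = 0.0314). Eln was lower in control mice too, at -0.75, and did not pass there (limma adjusted p = 0.0579). Eln passed in control mice without control replicate 3 (0.029) or smoke replicate 1 (0.0403) at 4 months or control replicate 1 at 6 months (0.0384). The control count was 0 without control replicate 1 at 4 months (Xist at 0.0721, the other 5 at 0.13), 1 without smoke replicates 2 or 3 at 4 months, smoke replicate 3 at 6 months or control replicate 2 at 6 months, 2 without control replicate 3 and 3 without smoke replicate 2 at 6 months. It was 30 and 578 without control replicates 2 and 3 at 4 months and 57 without control replicate 1 at 6 months. Saa3 was lost without any of 9 arrays (0.0534 to 0.135). In the smoke arm Eln was lost without smoke replicates 2 (0.0628) or 3 (0.063) at 6 months, and Xist without any single smoke array (0.0659 to 0.146) or control replicate 1 at 6 months (0.0576). In that arm 7 genes passed without control replicate 2 at 4 months. With only the control arrays in the fit the adjusted p of the 6 genes were 0.249 to 0.306, and with only the smoke arrays 26 genes passed. With array weights 175 genes passed in control and 372 in smoke-exposed mice. In control mice 24 passed with trend and robust spread, 20 with an offset of 50 and 0 with the replicate block.

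The labels give no length of exposure, so changes from 4 to 6 months in smoke-exposed mice do not separate age from longer exposure. Among lists, glucocorticoid targets were higher at 6 than at 4 months in control mice (median 0.60, 5 higher adjusted over the list alone, camera adjusted p = 0.000244, adjusted p = 0.381 with an estimated correlation) and lower in smoke-exposed mice (-0.39, 4 lower, 3.32e-05, adjusted p = 0.132 with an estimated correlation). Cell cycle genes were lower in control mice (-0.26, 7 lower, 0.000429, adjusted p = 0.664 with an estimated correlation) and higher in smoke-exposed mice (0.26, 8.51e-07, adjusted p = 0.502 with an estimated correlation). Extracellular matrix genes were lower in both arms, by -0.22 in control mice (1 higher and 5 lower adjusted over the list alone, 0.0126, adjusted p = 0.632 with an estimated correlation) and -0.37 in smoke-exposed mice (11 lower, 1.19e-11, adjusted p = 0.132 with an estimated correlation). Plasma cell and interferon genes were higher at 6 than at 4 months in smoke-exposed mice, by 0.61 (0.42 with genes at their bounds; 5 higher, 3.32e-05, adjusted p = 0.34 with an estimated correlation) and 0.17 (0.15 with genes at their bounds; 1 higher, 3.32e-05, adjusted p = 0.132 with an estimated correlation). B cell genes were higher in control (0.25, 0.0126, adjusted p = 0.796 with an estimated correlation) and smoke-exposed mice (0.30, 0.000702, adjusted p = 0.745 with an estimated correlation). All other p-values here are camera's too. Without control replicate 3 at 4 months, the calls in control mice of cell cycle (-0.24, 0.0699), matrix (-0.20, 0.169) and B cell genes (0.29, 0.076) were lost, and the glucocorticoid median was 0.39. The B cell call was also lost without control replicate 2 at 4 months (0.05, 0.4) or control replicate 3 at 6 months (0.16, 0.105). Its median was 0.50 and 0.44 without control replicate 1 at 4 and at 6 months. The cell cycle median was -0.43 without control replicate 2 at 4 months and -0.15 without control replicate 1 at 6 months. The glucocorticoid median was 0.39 without control replicate 2 at 6 months. In smoke-exposed mice the B cell call was lost without smoke replicate 3 at 6 months (0.21, 0.0705), and the plasma cell median was then 0.31.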

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

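The 2 tests of whether single arrays or the control arrays carry the pattern below were chosen after the result was seen, and the counts over other groupings of the arrays before. In 7 gene lists the smoke effect differed between 6 and 4 months by camera's test of the difference itself. The list median of the difference was 0.56 for cell cycle genes (camera adjusted p = 2.04e-12), -1.08 for glucocorticoid targets (1.87e-11) and 0.32 for interferon genes (2e-06). It was 0.42 for cytokines and chemokines (camera adjusted p = 3.05e-05), 0.78 for plasma cell and immunoglobulin genes (0.000152), -0.10 for extracellular matrix and fibroblast genes (0.0192) and 0.35 for T cell genes (0.0468). With an estimated correlation only the glucocorticoid list passed (adjusted p = 0.0272 with an estimated correlation), and the matrix and T cell lists had an adjusted p = 0.722 with an estimated correlation. Adjusted over the list alone, 2 matrix genes were lower, Lox and Ogn at -1.17 and -0.78, and no T cell gene passed in limma, with Zap70 at 0.58.

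The T cell call was lost without smoke replicate 2 at 4 months (median 0.26, adjusted p = 0.203), control replicates 1 (0.02, 0.604) or 3 (0.31, 0.302) at 4 months. It was also lost without smoke replicates 2 (0.32, 0.112) or 3 (0.29, 0.233) at 6 months or control replicate 1 at 6 months (0.27, 0.339). The matrix call was lost without smoke replicate 2 at 6 months (-0.06, 0.327). The matrix median was -0.19 without control replicate 3 at 4 months, -0.21 and -0.15 without smoke replicates 1 and 3 at 6 months and -0.15 without control replicate 2 at 6 months. The plasma cell median was 0.46 without control replicate 1 at 4 months and 0.49 without smoke replicate 3 at 6 months. The number of lists was 11 and 17 without smoke replicate 3 and control replicate 2 at 4 months, and 14 and 12 without smoke replicate 1 and control replicate 2 at 6 months.

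That a single array carries the whole set is argued against, since at least 5 of the 7 lists still passed at camera's preset correlation whichever array was left out. Whether the control arrays alone carry it stays open. At the preset correlation 5 of the 7 lists changed from 4 to 6 months in the smoke arrays in the direction of the difference, and 3 in the control arrays in the opposite direction. With an estimated correlation 0 of these lists passed in either arm, and with fry 1 in each. At the preset correlation cytokines were called in the control arrays (-0.40, camera adjusted p = 0.000709) and not in the smoke arrays (0.10, 0.319). Cytokines passed in the smoke arrays without smoke replicate 3 at 4 months (0.17, 0.0119) or smoke replicate 1 at 6 months (0.22, 0.016). Plasma cell genes were called in the smoke arrays (0.61, 3.32e-05) and not in the control arrays (-0.09). Chance cannot be excluded for the 7 lists: 54 of 100 groupings of the arrays by age within each treatment gave as many, the highest of the others 22. Age stays open as the biological difference the design names, and so does the length of exposure, which the labels do not give. Neither was tested, nor any batch or time of collection, since no source gave them.

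For single genes limma called 0 in the difference (875 at an unadjusted p below 0.05). All 100 groupings gave as many, as they must where the real count is 0, so they say nothing about chance. The highest of the others was 70 genes. The count was 2 without control replicate 3 at 4 months and 1 without control replicate 3 at 6 months. A grouping that calls 70 genes where the real one calls 0 may point to a structure of the samples, but it was the only one of the 99 others with over 10 genes. Their median was 0, 4 of them called any gene, and no test looked for such a structure. In the average over both ages the real count of 734 genes stood against a highest of 139 among 100 groupings by smoke within each age. That makes chance unlikely for this count without excluding it. For genes called at both ages 142 stood against 0. Other splits of the arrays of either age called 0 genes, so that 0 was nearly fixed beforehand and adds little. Within one comparison 3 against 3 arrays make 10 splits, too few for a share under 0.05. For smoke at 4 months the real and the highest other counts were 174 and 0 genes and 19 and 23 lists. At 6 months they were 535 and 0 genes and 22 and 18 lists. They were 6 and 9 genes and 7 and 18 lists for age in control mice, and 2 and 0 genes and 10 and 18 lists for age in smoke-exposed mice, where 5 of the 10 splits gave as many lists as the real one. The 7 lists of age in control mice were 13 without control replicate 2 and 2 without control replicate 3, both at 4 months.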

How the results depend on the processing

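All alternatives were chosen before the data were examined, and none was added. The counts of genes that smoke changed stayed within 1.5 times under the authors' values, the 4 other scalings or corrections, both filters, trend and robust spread, the mean of probes and the fit of only the arrays compared. Array weights, from 0.422 (control replicate 3 at 4 months) to 2.81 (smoke replicate 3 at 6 months), moved them from 174 to 648 at 4 months, from 734 to 1252 for the average and from 142 to 222 for genes called at both ages. The cause was not tested. With 1 array left out, which removes samples, the ranges were 87 to 371 genes at 4 months, 273 to 594 at 6 months, 451 to 956 for the average and 82 to 155 at both ages.

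The 6 genes that changed with age in control mice became 12 with the authors' values, 10 with no further background correction, 20 with an offset of 50, 2 without a filter and 10 with detection on all arrays. They became 24 with trend and robust spread, 175 with array weights, 0 with the replicate block, 0 with only the arrays compared and 0 to 578 with 1 array left out. The 2 in smoke-exposed mice became 1 with no further background correction, 6 with median scaling, 1 without a filter, 1 with detection on all arrays, 372 with array weights, 1 with the replicate block, 26 with only the arrays compared and 0 to 7 with 1 array left out. The 0 genes of the difference between ages became 1 with an offset of 50, 1 with median scaling, 2 with trend and robust spread, 13 with array weights, 2 with the mean of probes and 0 to 2 with 1 array left out. The fit of only the arrays compared gives no value for the average or the difference. The causes were not tested.

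Lists called by smoke numbered 19 at 4 months (12 with an estimated correlation, 12 with fry, 16 to 22 with 1 array left out) and 22 at 6 months (8 with an estimated correlation, 19 to 23 with 1 array left out). Those of the difference numbered 7 (12 with median scaling, 12 with array weights, 1 with an estimated correlation, 2 with fry, 5 to 17 with 1 array left out), and those of age in control mice 7 (11 with detection on all arrays, 0 with an estimated correlation, 3 with fry, 2 to 13 with 1 array left out). Those of age in smoke-exposed mice numbered 10 (0 with an estimated correlation, 1 with fry, 9 to 14 with 1 array left out). The cell cycle list at 4 months reversed without control replicate 2 (median 0.02, then -0.12, camera adjusted p = 0.0449), and its median ran from -0.12 to 0.12 with 1 array left out (0.0344 to 0.995). The heart list of age in smoke-exposed mice (median 0.02 with a test downward, camera adjusted p = 0.97) passed upward without smoke replicate 2 (0.23, 0.041) and downward without smoke replicate 1 (-0.35, 0.00621), both at 6 months. The causes were not tested. No gene that passed and was run under the alternatives changed sign.

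The replicate numbers do not pair the samples: of 18 same-numbered pairs across groups, 1 correlated over 0.1 in its deviations from the group means (range -0.374 to 0.229), and 6 matched their own number best. With the number as a block limma called 141 genes at 4 months, 426 at 6 months, 572 in the average and 116 at both ages. A slide or scan date block was not run, since no source gave one. The median change of all genes stayed within 0.05 log2 units under every scaling. Dim probes limit what can be seen, since changes near the background are compressed by the offset.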

Other observations

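The tests of the clock genes and of the second Xist probe were chosen after the results were seen, as was the list of platelet genes, and the test of Y-linked genes was chosen before. Of 11 tested platelet genes 4 passed in limma as lower in smoke-exposed lungs at 4 months: Gp5 (-1.48, adjusted p = 0.0155), Itga2b (-1.41, 0.0202), Treml1 (-1.33, 0.0218) and Gp9 (-1.17, 0.0426). The other 7 did not pass, among them Itgb3 and P2ry12, both at -0.03, Pf4 at 0.36 and Ppbp at -1.44 (0.116; 0.048 without smoke replicate 2 at 6 months). The median of the 11 was -1.13, and they were not tested as a list. Gp5, Itga2b and Treml1 were lost without smoke replicates 1 (adjusted p 0.0709 to 0.0945) or 2 (0.0602 to 0.096) or control replicate 1 (0.0644 to 0.0909). Itga2b and Treml1 were lost without smoke replicate 3 (0.0602 and 0.0817), and Itga2b without control replicate 2 (0.0632). Gp9 was lost without any 4-month array or replicate 3 of either arm at 6 months (0.0533 to 0.17). At 6 months the median was -0.63 and none passed in limma, Gp5 at -1.01 (adjusted p = 0.0571) and Treml1 at -0.94 (0.0614). Without control replicate 2 at 6 months Gp5 (-1.33, 0.0107), Treml1 (-1.16, 0.038) and Itga2b (-1.01, 0.015) passed. Without smoke replicate 2 at 6 months Treml1 (-1.24, 0.0176), Gp9 (-1.09, 0.0255) and Ppbp (-1.50, 0.0473) passed. The difference between the ages did not pass for any gene. Some genes of red blood cells were low on the same 4-month smoke arrays. Alas2 was at -1.16 (limma adjusted p = 0.0281), a call lost without any 4-month array but control replicate 1 (0.0535 to 0.143), and Slc4a1 at -1.69 (0.122; 0.0355 without control replicate 1 at 6 months). The mean deviation of the 7 erythroid genes from their averages over all arrays was -0.41, -0.59 and -0.39 on these arrays and 0.05, -0.08 and 0.13 on the controls. Whether the lungs differed in the blood they held was not tested.

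Lists of lining, muscle and stress genes were called at 6 months. Lower by camera were alveolar type 1 genes (median -0.25, adjusted p = 0.00839, adjusted p = 0.254 with an estimated correlation) and mesothelium (-0.50, 0.000175, adjusted p = 0.138 with an estimated correlation). Lower too were smooth muscle (-0.28, 0.0091, adjusted p = 0.373 with an estimated correlation), heart and pulmonary vein muscle (-0.32, 0.0245, adjusted p = 0.617 with an estimated correlation) and immediate early genes (-0.33, 0.0091, adjusted p = 0.387 with an estimated correlation). Adjusted over the list alone, 1 alveolar type 1, 4 mesothelial and 6 immediate early genes were lower, and none of smooth muscle or heart. The 85 tested genes of the alveolar type 1, mesothelium, smooth muscle, endothelial and matrix lists had a joint median of -0.26 at 6 months. Alveolar type 2, ciliated and club cell lists were at 0.14, 0.01 and -0.05. Whether incoming leukocytes diluted the RNA of these lung cells was not tested for these lists. The unfolded protein response was higher (0.17, 3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0372, adjusted p = 0.421 with an estimated correlation). Without smoke replicate 2 the calls of alveolar type 1 (-0.16, 0.0503), smooth muscle (-0.19, 0.0544), heart (-0.03, 0.565) and the unfolded protein response (0.19, 0.0821) were lost. Without smoke replicate 3 those of heart (-0.29, 0.0724) and the unfolded protein response (0.14, 0.134) were lost, the latter also without control replicate 1 (0.13, 0.196). Without control replicate 3 the calls of smooth muscle (-0.21, 0.0619), heart (-0.15, 0.179), immediate early genes (-0.21, 0.0759) and the unfolded protein response (0.14, 0.0839) were lost. The heart median was -0.71 without smoke replicate 1, and the alveolar type 1 median -0.16 without control replicate 3.

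At 4 months camera called mesothelium lower (-0.33, 4 lower adjusted over the list alone, 0.0093, adjusted p = 0.336 with an estimated correlation). It called neutrophil genes lower as well (-0.52, 1 higher and 1 lower, 0.044, adjusted p = 0.765 with an estimated correlation). Higher were mitochondrial respiration (0.08, 0.0358, adjusted p = 0.338 with an estimated correlation), glucocorticoid targets (0.30, 0.0358, adjusted p = 0.307 with an estimated correlation) and cholesterol synthesis (0.10, 1 higher, 0.044, adjusted p = 0.427 with an estimated correlation). Each call was lost without some arrays. Mesothelium was lost without control replicate 2 (-0.13, 0.125), and mitochondrial genes without smoke replicate 2 (0.09, 0.0618) or control replicate 2 (0.04, 0.185). Neutrophil genes were lost without smoke replicates 1 (-0.46, 0.0824) or 2 (-0.45, 0.188), control replicates 1 (-0.29, 0.394) or 3 (-0.40, 0.165), or control replicate 3 at 6 months (-0.52, 0.057). Glucocorticoid targets were lost without smoke replicate 3 (0.24, 0.0625) or control replicates 1 (0.13, 0.114) or 3 (0.23, 0.111). Cholesterol synthesis was lost without smoke replicate 2 (0.12, 0.125) or control replicates 1 (0.07, 0.114) or 2 (0.11, 0.0721). Without control replicate 3 the mitochondrial median was 0.13 and the cholesterol median 0.16, and the neutrophil median was -0.79 without smoke replicate 3 and -0.89 without control replicate 2.

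The neutrophil genes Lcn2 and Camp were at 1.66 and -3.23 at 4 months and did not pass. Camp was at 12.27 on control replicate 1 against 7.60 and 6.53 on the other 2, and its change was -1.50 without that replicate. Lcn2 passed at 4 months without control replicates 1 (2.15, limma adjusted p = 0.0322) or 2 (0.90, 0.0317). At 6 months Lcn2 rose by 2.77 (limma adjusted p = 0.00363), while the neutrophil list was at -0.23 (camera adjusted p = 0.887; -0.59 and 0.0159 without smoke replicate 2).

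Other lists did not pass camera at either age. Ciliated cells had medians of -0.00 at 4 and 0.01 at 6 months (adjusted p = 0.946 and 0.985). Club and goblet cells were at 0.03, with a mean of -0.03 and a test upward, and at -0.05, with a mean of 0.05 and a test downward (0.714 and 0.99). Skeletal muscle was at -0.17 and -0.10, the latter with a test upward (0.835 and 0.99), and adipose tissue at -0.53 and -0.11 (0.0851 and 0.765). Liver was at 0.04 and 0.13 (0.731 and 0.45), cartilage and trachea at -0.12 and 0.07 (0.685 and 0.837), and ribosomal proteins at -0.04 and -0.07 (0.478 and 0.194). Thymocytes were at 0.01, with a mean of -0.02, and at -0.20 (0.968 and 0.45), and hypoxia genes at 0.07 and at 0.11, the latter with a mean of -0.05 (0.608 and 0.837). The erythroid list was at -0.27 and at -0.03, the latter with a mean of 0.17 and a test upward (0.0851 and 0.82). Eosinophils and nerve, with 3 tested genes each, had medians of 0.12 and 0.03 at 4 months and 1.42 and 0.24 at 6 months. Adipose tissue passed at 4 months without control replicate 2 at 4 months (-0.49, 0.0343) or smoke replicate 3 at 6 months (-0.53, 0.0105), and at 6 months without smoke replicate 3 (-0.57, 0.00348). The erythroid list passed at 4 months without control replicate 2 at 4 months (-0.41, 0.0343) or smoke replicate 1 at 6 months (-0.27, 0.0322).

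Some lists called at one age were not called at the other. At 6 months interferon genes were at -0.03, with a mean of 0.01 and a test upward (camera adjusted p = 0.904), NK cells at -0.12 (0.0577) and mast cells at -0.26 (0.0847). Cholesterol synthesis was at -0.01, with a mean of 0.07 and a test upward, and mitochondrial genes at 0.03 (both 0.447). The NK list passed without smoke replicate 1 at 4 months (-0.12, 0.0494), smoke replicate 2 at 6 months (-0.13, 0.0274) or control replicate 1 at 6 months (-0.21, 0.0389), and the mast cell list without control replicate 1 at 6 months (-0.35, 0.0249). At 4 months MHC class II and dendritic cell genes were at 0.06 (camera adjusted p = 0.12), cell cycle at 0.02 (0.664), alveolar type 1 at -0.07 (0.288) and matrix genes at -0.06 (0.759). Smooth muscle was at -0.15 (0.698), heart at -0.28 (0.133), immediate early genes at -0.14 (0.618) and the unfolded protein response at 0.07 (0.0801). The MHC class II and dendritic cell list passed without control replicate 1 (0.09, 0.00426). Cell cycle passed upward without control replicate 1 (0.12, 0.0344) and downward without control replicate 2 (-0.12, 0.0449). Heart passed without smoke replicate 3 (-0.29, 0.0418), control replicate 2 (-0.38, 0.045) or smoke replicate 1 at 6 months (-0.26, 0.0433). The unfolded protein response passed without smoke replicate 1 at 4 months (0.13, 0.0069) or at 6 months (0.07, 0.0473).

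At 6 against 4 months, control mice had lower cytokine genes (median -0.40, 1 lower adjusted over the list alone, camera adjusted p = 0.000709, adjusted p = 0.632 with an estimated correlation) and neutrophil genes (-0.64, 0.0397, adjusted p = 0.796 with an estimated correlation). They had higher mitochondrial genes (0.18, 0.00125, adjusted p = 0.493 with an estimated correlation). Smoke-exposed mice had lower endothelial (-0.16, 2 lower adjusted over the list alone, 7.5e-05, adjusted p = 0.34 with an estimated correlation) and smooth muscle genes (-0.24, 0.00374, adjusted p = 0.532 with an estimated correlation). They had higher mitochondrial (0.10, 0.00988, adjusted p = 0.408 with an estimated correlation) and erythroid genes (0.55, 3 higher adjusted over the list alone, 0.0182, adjusted p = 0.517 with an estimated correlation). The mean deviation of the erythroid genes was 0.94 on smoke replicate 1 at 6 months against 0.03 and -0.08 on the other 2, and without that replicate the call was lost (median 0.51, 0.0612). Without smoke replicate 2 at 6 months the calls of mitochondrial (0.08, 0.102) and smooth muscle genes (-0.15, 0.0644) in smoke-exposed mice were lost. In control mice the cytokine call was lost without control replicate 3 at 4 months (-0.26, 0.0778). The neutrophil call was lost without control replicates 1 (-0.19, 0.495) or 3 (-0.55, 0.169) at 4 months or 1 (-0.82, 0.143) or 3 (-0.46, 0.193) at 6 months. Without control replicate 2 at 4 months the neutrophil median was -1.10 and the mitochondrial 0.11.

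Clock genes of opposite phase moved apart under smoke. The 9 tested genes that peak with Dbp had median changes of 1.20 at 4 and 1.06 at 6 months, and the 4 of opposite phase of -0.90 and -1.06, differences of 2.10 and 2.12 (exact permutation p = 0.00699 at both ages, over genes, which are not independent). With Npas2 at its bound at 6 months the median of the opposite phase was -0.995 and the difference 2.05. Dilution of lung cells by leukocytes without these RNAs would lower genes of both phases alike, and that 2.10 argues against it. Leukocytes that carry clock gene RNA of their own could move the phases apart, which was not tested. Normalization is argued against by a lowest difference of 1.51 over the background and scaling alternatives. Smoke and control lungs collected at different times of day could give the 2.12 as well as a change of the clock under smoke, and the 2 cannot be told apart, because the labels give no collection times. Over 85 structural lung genes the medians were -0.16 at 4 and -0.26 at 6 months.

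Xist was lower at 6 than at 4 months in both arms, by -1.71 in control and -1.51 in smoke-exposed mice. A fault of a single probe is argued against, since the other tested Xist probe was at -0.999 and -0.58. Male mice among the 6-month arrays are argued against too: the Y-linked genes Kdm5d and Eif2s3y were detected on no array, Uty, detected on 10 of the 12 arrays (6 at 4 and 4 at 6 months), was at -0.22 in both arms, and the highest of the 2 arms' medians over these 3 genes was 0.00736. That argument is limited, since all mice are labelled female and no male array shows that these probes respond. The values of Uty, 4.70 to 5.42, lay close to the lowest detected on the arrays (4.85 to 4.94). Age stays open and untested, and no source gave a batch. With detection asked on all arrays that other probe stood for Xist, with a limma adjusted p of 0.0368 in control mice (0.00332 to 0.249 over all alternatives) and 0.186 in smoke-exposed mice (0.00377 to 0.186), and leaving out arrays ended the calls too, up to 0.0721 and 0.146.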
